A study of Mus musculus with 24 samples.

How the data were processed

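Messenger RNA of whole subcutaneous white adipose tissue from the inguinal region of C57BL/6J mice was sequenced in 24 libraries. Per the labels' protocols, the lymph node was taken out of the fat before freezing, RNA was extracted with Trizol and RNeasy columns, only RNA with an integrity number of at least 7 was sequenced, and libraries were made with the Illumina TruSeq stranded mRNA kit. The values are the whole-number read counts per gene that the authors deposited in 2 tables, one holding the 12 chow libraries and the other the 12 high-fat diet (HFD) libraries. The submitters' processing notes name bcl2fastq, FastQC, STAR 2.4.1, DESeq2 and the mm10 build. Per the labels, base calls were converted with bcl2fastq 2.20.0.422 for chow and bclfastq 2.16.0.10 for HFD. The counting tool, the gene annotation and whether counting used strand are not given in the sources used here. Nothing was normalised before deposit, as far as the whole numbers and unequal library totals show.

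The tables held 39,017 genes for chow and 38,483 for HFD, of which 38,013 identifiers were shared, 1004 were in the chow table alone and 470 in the HFD table alone. Of the shared identifiers, 1347 had different symbols in the 2 tables, so genes were joined by identifier. Gene positions, biotypes and exon overlaps came from GENCODE M21 on GRCm38 (mm10), in which 96.6% of the chow and 95.4% of the HFD identifiers were found, and coordinates are 1-based. Genes that overlap another annotated gene by exons on either strand are given with the overlapping share of their exon length, since their counts are uncertain when strand use is not known. Every column of per-sample counts was used.

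The labels put 6 libraries in each of 4 groups: WT-Tg and D316A-Tg on chow, and WT-Tg and D316A-Tg on HFD. Libraries are named by group and by the number in their title, 1 to 6 for WT-Tg and 7 to 12 for D316A-Tg on each diet. Replicate libraries differed by far more than sampling noise, the lowest chi-square per degree of freedom of any pair within a group being 13.5, so no library was treated as a copy of another. Each library held between 13,254,536 and 22,748,132 counts. At this depth, 1 count is under 0.1 CPM, and the spread between libraries, not counting error, limits the precision of genes above a few CPM.

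Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with robust empirical Bayes, TMM scaling and the filterByExpr filter on the groups compared. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The D316A comparisons were fitted within each diet. The difference of the D316A effect between diets and the comparison of HFD with chow WT-Tg were fitted on genes present in both tables. Log2 fold changes are given with their standard errors (SE). CPM values are counts scaled to a TMM-adjusted library of 1e6 counts, as mean ± SD over the 6 libraries of a group, and log2 CPM was taken with a prior count of 2.

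Gene lists, 32 in number with 605 genes, were fixed before the data were examined, as were the tests, the groups and most alternatives. They were AMPK subunits, brown and beige adipocyte, creatine cycling, sarcoplasmic calcium cycling, skeletal muscle contractile, myogenic lineage, nuclear-encoded oxidative phosphorylation, mitochondrial genome transcripts, TCA cycle, fatty acid oxidation, de novo lipogenesis, triglyceride synthesis, lipolysis, cholesterol synthesis, glucose uptake and glycolysis, mature adipocyte, adipocyte progenitor and fibroblast, collagen and matrix, macrophage, inflammatory cytokines, T lymphocyte, B lymphocyte, endothelial, smooth muscle and pericyte, mammary and luminal epithelium, skin, Schwann and neuronal, blood cells, immediate early response, circadian clock, cell division and sex-linked genes. The symbols of 4 list genes, Mrln, Msmo1, Ighd and Ciart, were not matched. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 32 lists of a comparison, and again with an estimated correlation and with fry. A list score is the mean log2 CPM of its genes in a library.

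Prkag1 and Ucp1 are always reported. The other named genes follow a rule fixed in advance: genes with the largest fold changes in each direction among those called with a mean of at least 5 CPM in the higher group, and up to 4 members with the lowest adjusted p of each list described. Predicted genes, clones, antigen receptor segments and pseudogenes were counted and not named. Which of the genes and lists under this rule are described at length was settled after their values were seen.

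Alternatives were RLE or upper-quartile scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter beyond 1 count, a mean count of at least 50, no robust step, all 24 libraries in a single fit, the skeletal muscle or B lymphocyte score of each library as a covariate, the replicate number as a block, and leaving out each library. After the data were seen, fits were added with a term for libraries whose B lymphocyte score was above 3 log2 CPM, called lymphocyte-rich here, and fits without those libraries, and a cohort fit without genes at 0 in all 12 libraries of one table. A bound of 3 was chosen because it lies in the gap between both kinds of library in each table.

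The gene tests were tested on simulated counts drawn from the real means, spreads and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. The chow comparison recovered 29 of the 2-fold and 71 of the 4-fold changes with 5.66% false calls among its calls. For HFD these were 59, 96 and 2.38%, for the difference between diets 31, 61 and 3.13%, and for the comparison of WT-Tg between diets 51, 84 and 6.71%. In each simulation the 1 shifted list was called and 0 of the other 31 lists. Genes were drawn independently of each other, without the lymphocyte or muscle differences between the real libraries. The simulation therefore does not show how list tests or false calls behave when genes vary together.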

Results

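Inguinal subcutaneous white adipose tissue was profiled by RNA sequencing in mice carrying a transgene for the γ1 subunit of AMP-activated protein kinase (AMPK), a heterotrimeric kinase that responds to the energy state of the cell. WT-Tg mice carried the wild-type subunit and D316A-Tg mice a gain-of-function form of it. Mice fed chow were 16 weeks old and mice fed a high-fat diet (HFD, 45% fat) were 24 weeks old, with 6 libraries in each of the 4 groups. Library totals were 13,254,536 to 17,685,717 counts for WT-Tg on chow, 14,756,322 to 17,766,546 for D316A-Tg on chow, 19,063,635 to 22,748,132 for WT-Tg on HFD and 16,373,731 to 20,774,533 for D316A-Tg on HFD. The labels do not state that the 6 libraries of a group came from separate animals, so p-values measure the spread between these samples, which can be technical.

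Markers of other cell types differed widely between libraries of the same group. The mean log2 CPM of the B lymphocyte list, which includes the B cell receptor component Cd79a, lay between 6.20 and 7.53 in 6 chow libraries (WT-Tg 1 to 4, D316A-Tg 8 and 11) and at most at 0.45 in the other 6. On HFD it was 4.37 or more in 5 libraries (WT-Tg 3, D316A-Tg 7, 8, 9 and 11) and at most 2.32 in the other 7. Lymphocyte-rich libraries were thus 4 of 6 in WT-Tg and 2 of 6 in D316A-Tg on chow, and 1 of 6 and 4 of 6 on HFD. The skeletal muscle contractile list, which holds myosin, actin and troponin genes of striated muscle, scored 0.31 to 6.93 in WT-Tg and -0.37 to 4.06 in D316A-Tg on chow, and 0.03 to 2.90 in WT-Tg and 2.83 to 8.15 in D316A-Tg on HFD.

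**Figure D1:**
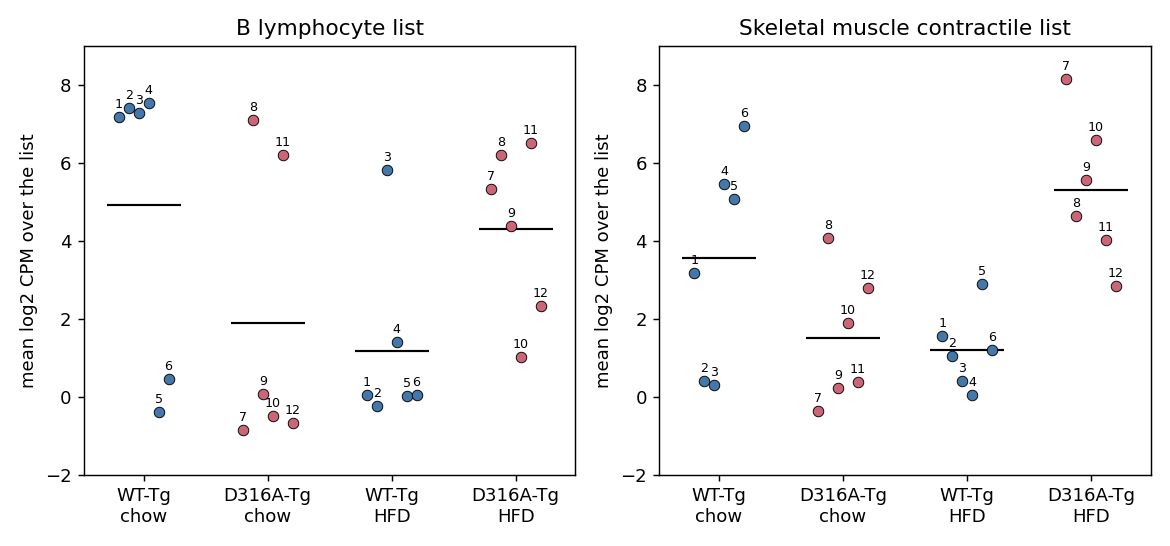
Mean log2 CPM of the B lymphocyte list (left) and the skeletal muscle contractile list (right) in each library, by group; points are libraries numbered by replicate and horizontal lines are group means. B lymphocyte scores lay on both sides of the bound of 3 in all 4 groups, with library 12 of HFD D316A-Tg at 2.32 and library 9 at 4.37. Muscle scores of HFD D316A-Tg libraries lay between 2.83 and 8.15.

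Prkag1, the gene of the transgenic subunit (ENSMUSG00000067713, chromosome 15, 98812797 to 98831521, minus strand), had similar levels in both genotypes. On chow it was at 410 ± 90.5 CPM (SD, n = 6) in WT-Tg, with libraries from 334 to 582, and 386 ± 88.3 CPM in D316A-Tg, with libraries from 296 to 535, a log2 fold change of -0.09 (SE 0.18, adjusted p = 0.748). On HFD the means were 310 ± 15.8 and 368 ± 165 CPM, with libraries from 292 to 337 and from 246 to 690, a log2 fold change of 0.25 (SE 0.22, adjusted p = 0.445). Another gene overlaps 43.7% of its exon length, and the sources do not state whether transgene reads were counted on it. The level of Prkag1 therefore does not check the genotype labels.

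The chow comparison asked which genes differed between the gain-of-function and the wild-type subunit in mice fed chow. On chow, lists of mitochondrial respiration, fatty acid oxidation and de novo lipogenesis had higher medians in D316A-Tg adipose tissue, and lists of the vessel wall lower ones. Camera called 22 of 32 lists, and 0 with an estimated correlation (lowest adjusted p = 0.366). Lymphocyte-rich libraries were 4 of 6 in WT-Tg and 2 of 6 in D316A-Tg. Of the 75 nuclear-encoded subunits of oxidative phosphorylation, 58 rose and 0 fell, with a median log2 fold change of 0.89. Among genes typical of brown and beige fat, Ppargc1a rose 2.06-fold, Cidea 2.55-fold and Cox8b 3.14-fold, while Ucp1 did not pass the test. In all, 1303 of 15,249 genes were called, 808 higher and 495 lower, and 307 of them differed at least 2-fold.

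Ucp1, the mitochondrial uncoupling protein of brown fat (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452, plus strand), was at 83.2 ± 122 CPM in WT-Tg and 301 ± 237 CPM in D316A-Tg on chow, a log2 fold change of 1.85 (SE 0.99, adjusted p = 0.224). The brown and beige adipocyte list had a median log2 fold change of 0.92, with 6 of 22 members higher and 0 lower, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.68e-06, and adjusted p = 0.366 with an estimated correlation). Ppargc1a, a coactivator that drives mitochondrial biogenesis (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726), went from 10.2 ± 3.74 to 21.1 ± 3.56 CPM (log2 fold change 1.04, SE 0.22, adjusted p = 0.0235). Cidea, a lipid droplet protein abundant in brown fat (ENSMUSG00000024526, chromosome 18, 67343604 to 67367785), went from 177 ± 87.2 to 452 ± 88.3 CPM (1.35, SE 0.33, adjusted p = 0.0345). Cox8b, a cytochrome c oxidase subunit of muscle and brown fat (chromosome 7, 140898945 to 140900446), had a log2 fold change of 1.65 (SE 0.39). Gyk, glycerol kinase (chromosome X, 85701937 to 85776819), had one of 1.44 (SE 0.26). Leaving out single libraries ended the calls of Ppargc1a, Cidea, Cox8b and Gyk (highest adjusted p = 0.0759, 0.086, 0.0797 and 0.0517).

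Mitochondrial lists moved together on chow. Adjusted over the list alone, 73 of 75 nuclear-encoded oxidative phosphorylation genes rose (camera adjusted p = 1.45e-30, and adjusted p = 0.366 with an estimated correlation). Among 100 splits of the chow libraries, the real one included, camera also called this list in 79 of the other splits. Cox7b of complex IV (ENSMUSG00000031231, chromosome X, 106015700 to 106022450) rose from 212 ± 53 to 481 ± 96.8 CPM (log2 fold change 1.18, SE 0.20, adjusted p = 0.0136), and Ndufs5 of complex I from 16.3 ± 5.06 to 46.5 ± 13 CPM. Of the 11 mitochondrial genome transcripts tested 8 rose, all 11 adjusted over the list alone, with a median of 0.98. One of them was mt-Nd6, a complex I subunit, at a log2 fold change of 1.19 (SE 0.21). The TCA cycle list had a median of 0.90 with 12 of 17 members higher, 16 adjusted over the list alone, among them Pdha1, a subunit of pyruvate dehydrogenase (1.40, SE 0.28), which another gene overlaps over 16.1% of its exons. The fatty acid oxidation list had a median of 0.99 with 11 of 25 members higher, and 23 higher and 1 lower adjusted over the list alone. Hadhb, a subunit of the trifunctional protein of fatty acid oxidation (ENSMUSG00000059447, chromosome 5, 30155248 to 30184593), rose from 69.3 ± 22.4 to 155 ± 26.4 CPM (1.16, SE 0.23, adjusted p = 0.0203). Camera adjusted p-values of these 3 lists were 2.84e-08, 1.14e-10 and 5.06e-11, and the adjusted p was 0.366 for each with an estimated correlation. Leaving out single libraries ended the calls of Hadhb and Pdha1 (highest adjusted p = 0.0601 and 0.0596), and that of Cox7b held without any library.

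Lipid synthesis lists also had higher medians. De novo lipogenesis had a median of 1.10 with 8 of 20 members higher, 13 adjusted over the list alone (camera adjusted p = 4.17e-06, and adjusted p = 0.463 with an estimated correlation). Its members included Thrsp, a regulator of lipogenesis (2.59-fold), and Acacb, acetyl-CoA carboxylase 2 (2.30-fold). Triglyceride synthesis had a median of 0.84 with 1 of 11 members called, the acyltransferase Gpam (2.44-fold), and 5 adjusted over the list alone (0.000193, and adjusted p = 0.463 with an estimated correlation). Cholesterol synthesis had a median of 0.55 with 6 of 22 members higher, and 11 higher and 1 lower adjusted over the list alone (0.000181, and adjusted p = 0.375 with an estimated correlation), among them the isomerase Idi1 (2.12-fold). Glucose uptake and glycolysis had a median of 0.62 with 5 members higher and 1 lower of 25, and 10 and 2 adjusted over the list alone (0.000418, and adjusted p = 0.499 with an estimated correlation). Its member Eno1, enolase, rose 2.78-fold, but its reads can be shared with its near-identical copy Eno1b. Lipolysis (median 0.35, 1 of 12 higher, the droplet protein Plin5) and mature adipocyte genes (median 0.66, 0 of 16 called) had camera adjusted p-values of 0.0261 and 0.00305, and the adjusted p was 0.585 for both with an estimated correlation. With a term for lymphocyte-rich libraries the medians of triglyceride synthesis, glycolysis, mature adipocyte and lipolysis were 0.44, 0.36, 0.27 and 0.20, and the lipolysis call ended (adjusted p = 0.152). Leaving out single libraries ended the calls of Thrsp, Acacb, Gpam, Idi1 and Plin5 (highest adjusted p = 0.0943, 0.0958, 0.0575, 0.0685 and 0.111). Dropping the filter ended those of Thrsp, Acacb and Plin5.

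Endothelial, smooth muscle and immediate early lists had lower medians on chow. The endothelial list had a median log2 fold change of -0.74 with 3 of 13 members lower, 6 adjusted over the list alone, and Vwf, the von Willebrand factor (ENSMUSG00000001930, chromosome 6, 125546774 to 125686679), went from 27.7 ± 8.65 to 11.2 ± 1.92 CPM (-1.31, SE 0.20, adjusted p = 0.00981). The smooth muscle and pericyte list had a median of -0.90 with 4 of 13 members lower, 8 adjusted over the list alone, including the receptor Notch3 (-1.13, SE 0.17) and smooth muscle actin Acta2 (-1.21, SE 0.29). Camera gave adjusted p-values of 0.000181 and 0.000237 for these lists, and the adjusted p was 0.463 and 0.366 with an estimated correlation. Immediate early genes had a median of -0.63 with 2 of 14 lower, 6 adjusted over the list alone, including the stress-response factor Atf3 (-1.18, SE 0.32, camera adjusted p = 0.00206, and adjusted p = 0.366 with an estimated correlation). The calls of Acta2 and Atf3 ended without single libraries (highest adjusted p = 0.0854 and 0.11), and those of Vwf and Notch3 held without any library.

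Lists of macrophages (median -0.91), inflammatory cytokines (-0.81), T lymphocytes (-1.09), B lymphocytes (-1.56) and cell division (-0.63) had camera adjusted p-values of 0.00388, 0.0298, 0.021, 0.0169 and 0.0181 in the lower direction, with 1 member called among them, a cytokine. With an estimated correlation the adjusted p was 0.585, 0.463, 0.678, 0.639 and 0.639. Lymphocyte-rich libraries were 4 of 6 in WT-Tg and 2 of 6 in D316A-Tg, and with a term for them the 5 medians were -0.52, -0.52, -0.21, -0.63 and -0.14. The macrophage call stayed (adjusted p = 0.0204, and 0.602 with an estimated correlation as well), and those of cytokines, T lymphocytes and cell division ended (0.103, 0.325 and 0.294). The term is set by the B lymphocyte score, so it decides nothing about that list. The T lymphocyte call was also lost without any of 6 libraries (highest adjusted p = 0.0796). In the leave-one-out fit with its highest adjusted p, the macrophage list had a median of -0.45 (camera adjusted p = 0.0189). The skeletal muscle contractile list had a median of -3.28 with 0 of 29 members called by edgeR (camera adjusted p = 0.000471). It was -1.89 in the leave-one-out fit with the highest adjusted p (0.0182). The sarcoplasmic calcium cycling list had a median of -1.49 with 2 of 17 lower, 5 adjusted over the list alone (camera adjusted p = 0.021). The adjusted p was 0.585 for both with an estimated correlation, and the calcium cycling call was lost without any of 2 libraries (highest adjusted p = 0.0941) and with a mean count of at least 50 (-2.57, adjusted p = 0.0581). Their levels followed the muscle score of single libraries: Ryr1, the calcium release channel of skeletal muscle, was at 263 CPM in WT-Tg 6 and at 2.67 CPM in WT-Tg 2 (log2 fold change -4.13, adjusted p = 0.0531). Jph2, a junctional membrane protein of muscle, fell by 3.61 on the log2 scale (SE 0.99), a call that ended without any of 10 libraries (highest adjusted p = 0.111) and with no filter (0.072).

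Sex-linked genes, included as a check of the libraries, had 2 of 4 members higher on chow: the Y-linked genes Ddx3y went from 63.9 ± 5.84 to 95.6 ± 4.89 CPM and Uty from 18.1 ± 2.52 to 34.4 ± 8 CPM (list median 0.38, camera adjusted p = 0.00534, and adjusted p = 0.366 with an estimated correlation). The 10 lists that camera did not call had medians of -0.09 for AMPK subunits, -0.47 for creatine cycling, -0.66 for myogenic lineage, 0.02 for adipocyte progenitor and fibroblast, -0.20 for collagen and matrix, 0.89 for mammary and luminal epithelium, 0.11 for skin, -0.97 for Schwann and neuronal, -0.20 for blood cells and 0.34 for the circadian clock. Their adjusted p-values were 0.926, 0.235, 0.372, 0.818, 0.242, 0.431, 0.805, 0.0736, 0.968 and 0.372. The adipocyte progenitor and fibroblast list had a positive median and a mean of -0.10. With a term for lymphocyte-rich libraries camera called collagen and matrix, creatine cycling and Schwann and neuronal genes in the lower direction (adjusted p = 2.49e-06, 0.0159 and 0.0123). With an estimated correlation as well, the adjusted p was 0.291, 0.291 and 0.467.

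The largest increases on chow included Rab6b, a small GTPase of Golgi transport (ENSMUSG00000032549, chromosome 9, 103111787 to 103185276), from 1.61 ± 0.494 to 18.6 ± 10.4 CPM (log2 fold change 3.52, SE 0.47, adjusted p = 0.00499). The long noncoding RNA gene Gdap10 (3.43, SE 0.39), Zbed6 (2.71, SE 0.36, with 91.8% of its exons inside another gene), the soluble adenylyl cyclase Adcy10 (2.17, SE 0.34) and the kinase Hipk2 (1.74, SE 0.22) also rose. The largest decreases included Gdpd3 (-4.30, SE 0.94, 13.6% exon overlap), which was above 50 CPM in WT-Tg 1, 2 and 3 and at or under 3.24 CPM in every other chow library, Folh1 (-3.40, SE 0.77) and integrin β4, Itgb4 (-1.63, SE 0.32). Gdpd3 was at -2.87 with a term for lymphocyte-rich libraries and not called (adjusted p = 0.0681). Single libraries left out ended the calls of Gdpd3, Folh1 and Itgb4 (highest adjusted p = 0.0698, 0.0735 and 0.0582).

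The number of chow calls rested on single libraries: it was 420, 383, 215 and 349 without WT-Tg 1, 2, 3 and 4, 140, 205, 244 and 141 without D316A-Tg 7, 9, 10 and 12, and 3360 without D316A-Tg 8. It was 67 with the muscle score as a covariate and 4412 with a term for lymphocyte-rich libraries, of which 2093 were higher (47.4%, against 62% without the term; 46.6% higher of 10,826 calls with voom and 48.5% of 3729 with the B lymphocyte score). Of the 1303 calls, 1301 were also called with that term, 854 without the lymphocyte-rich libraries and 67 with the muscle score. With the term all 1303 kept their direction, which is no separate evidence, as they were picked in a fit of the same libraries.

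**Figure D2:**
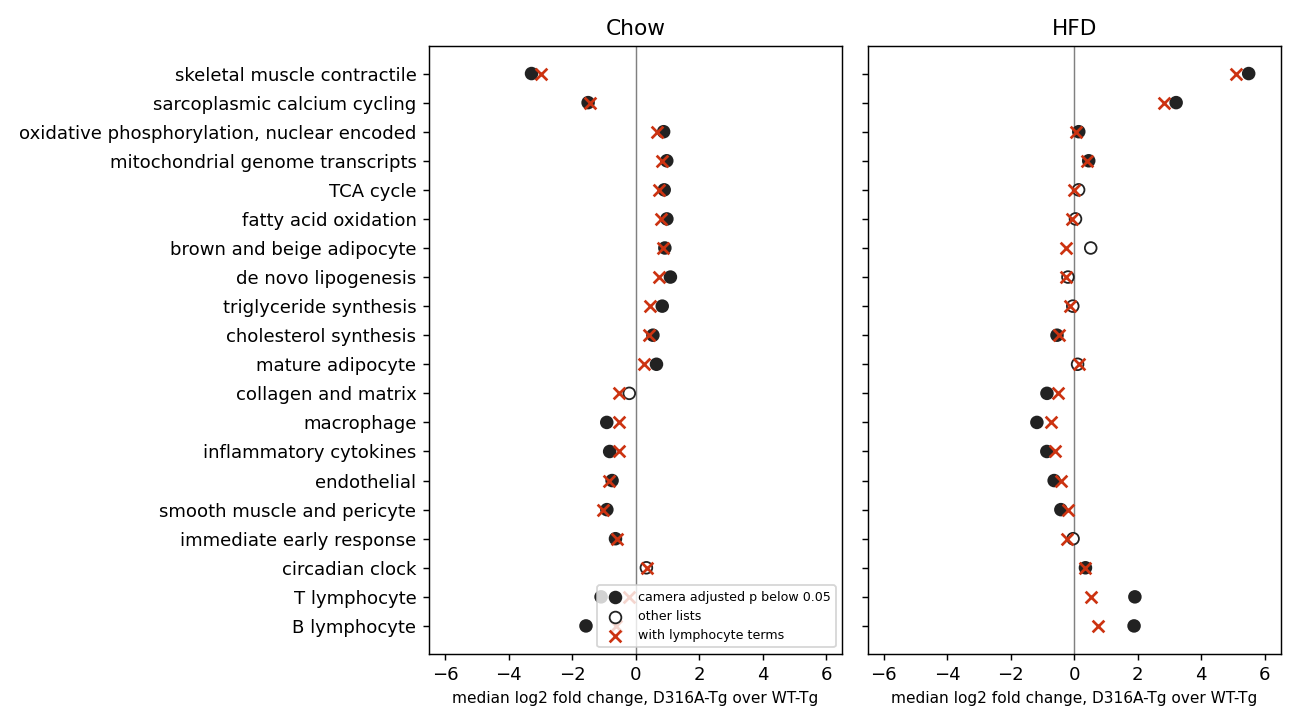
Median log2 fold change of D316A-Tg over WT-Tg over the members of 20 gene lists, on chow (left) and HFD (right); filled points have a camera adjusted p below the threshold of 0.05, open points do not, and crosses are medians from the fit with a term for lymphocyte-rich libraries. On chow the oxidative phosphorylation median was 0.89 and 0.67 with the term, and on HFD the contractile list median was 5.50 and 5.10 with it.

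The HFD comparison asked the same of mice on the high-fat diet. Here the largest differences were in striated muscle genes: 28 of 29 tested members of the contractile list rose in D316A-Tg, with a median log2 fold change of 5.50. Lists of cholesterol synthesis, macrophages, blood vessels and the extracellular matrix had lower medians, with 10 of 22, 6 of 23, 5 of 13 and 3 of 30 members lower, and oxidative phosphorylation had a median of 0.15. Camera called 16 of 32 lists, and 0 with an estimated correlation (lowest adjusted p = 0.511). Lymphocyte-rich libraries were 1 of 6 in WT-Tg and 4 of 6 in D316A-Tg. The adipokine Cfd rose 5.28-fold and Pck1, an enzyme of glycerol synthesis in fat, 3.42-fold. Both calls ended with a term for lymphocyte-rich libraries, at log2 fold changes of 1.99 for Cfd and 1.42 for Pck1, which was at 1.78 without it (adjusted p = 0.0624 and 0.0735). In all, 1241 of 14,649 genes were called, 661 higher and 580 lower, 391 of them at least 2-fold.

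Contractile genes rose in all but 1 tested member, also adjusted over the list alone (camera adjusted p = 3.96e-17, and adjusted p = 0.511 with an estimated correlation). Myh4, a fast myosin heavy chain (ENSMUSG00000057003, chromosome 11, 67238029 to 67260446), was at 10.3 ± 13 CPM in WT-Tg and 1410 ± 2460 CPM in D316A-Tg (log2 fold change 7.09, SE 1.65, adjusted p = 0.0278), with libraries from 5.63 to 6340 CPM. Actn3, an actinin of fast fibres (7.21, SE 1.38), Mylk4, a myosin kinase (7.47, SE 1.36), and Ckm, the muscle creatine kinase (6.94, SE 1.44, with 15.5% exon overlap), rose as well. The sarcoplasmic calcium cycling list had a median of 3.21 with 10 of 17 members higher and 1 lower, and 11 and 2 adjusted over the list alone (0.00128, and adjusted p = 0.511 with an estimated correlation). Atp2a1, the fast-fibre calcium pump SERCA1 (ENSMUSG00000030730, chromosome 7, 126445858 to 126463108, 21.9% exon overlap), went from 5.34 ± 6.89 to 703 ± 1130 CPM (7.04, SE 1.43, adjusted p = 0.0222). Triadin, Trdn, rose 24.9-fold. Ryr2, the calcium release channel known from heart (ENSMUSG00000021313, chromosome 13, 11553102 to 12106945), instead went from 18.6 ± 2.71 to 6.54 ± 3.98 CPM (-1.50, SE 0.31, adjusted p = 0.0224). None of these genes was called with a term for lymphocyte-rich libraries. Atp2a1 was then at 6.93 (adjusted p = 0.0731), Myh4 at 6.88 (0.101) and Ryr2 at -1.24 (0.0731). The calls of Myh4, Ckm and Atp2a1 ended without single libraries (highest adjusted p = 0.064, 0.0542 and 0.0522).

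Creatine cycling had 2 of 7 members higher, Ckm and the mitochondrial muscle creatine kinase Ckmt2 (73.4-fold), and 1 lower, and its median of -0.23 and mean of 1.57 differed in sign (camera adjusted p = 0.846). Each D316A-Tg HFD library but 12 had a muscle score above 4, and every WT-Tg HFD library one of at most 2.90, so that the score and the genotype went together (correlation 0.829 over the 12 libraries). With the muscle score as a covariate edgeR called 0 genes, with 921 at an unadjusted p under 0.05, and without it DESeq2 called 2937 and voom 4312.

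Ucp1 on HFD was at 120 ± 123 CPM in WT-Tg and 174 ± 387 CPM in D316A-Tg (log2 fold change 0.54, SE 1.35, adjusted p = 0.802), and the D316A-Tg mean rested on library 7 at 964 CPM. The log2 fold change was -3.71 with a term for lymphocyte-rich libraries (adjusted p = 0.517). The brown and beige adipocyte list had a median of 0.52 with 0 of 22 members called by edgeR (camera adjusted p = 0.846), and a median of -0.25 with a term for lymphocyte-rich libraries. Nuclear-encoded oxidative phosphorylation genes had a median of 0.15 with 0 of 75 called by edgeR (camera adjusted p = 0.0186, and adjusted p = 0.931 with an estimated correlation). This call was lost without any of 4 libraries, with a median of -0.00 in the fit with the highest adjusted p (0.923), and with a term for lymphocyte-rich libraries (0.06, adjusted p = 0.134). Mitochondrial genome transcripts had a median of 0.46 with 2 of 13 higher (0.000496, and adjusted p = 0.586 with an estimated correlation). Medians of the TCA cycle, fatty acid oxidation, de novo lipogenesis and triglyceride synthesis were 0.14, 0.04, -0.19 and -0.04, and none of these 4 lists was called. The triglyceride list's mean was 0.02. Their members Thrsp (1.67, SE 0.35) and Pck1 (1.78, SE 0.33) rose, as did the β3 adrenergic receptor Adrb3 of the lipolysis list (1.53, SE 0.35, 24.9% exon overlap) and Cfd, complement factor D (5.28-fold), from 838 ± 398 to 4420 ± 1810 CPM. Thrsp, Pck1, Adrb3 and Cfd were at 0.99, 1.42, 1.12 and 1.99 with a term for lymphocyte-rich libraries and not called (adjusted p = 0.181, 0.0735, 0.192 and 0.0624). Leaving out single libraries ended the calls of Thrsp and Adrb3 (highest adjusted p = 0.0542 and 0.062).

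Cholesterol synthesis was lower on HFD, with a median of -0.54, 10 of 22 members lower and 0 higher, and 16 lower adjusted over the list alone (camera adjusted p = 8.97e-08, and adjusted p = 0.511 with an estimated correlation). D316A-Tg 12 scored 5.708 for this list, within the WT-Tg range of 5.643 to 5.964. The other D316A-Tg libraries scored 4.833 to 5.324. Hmgcs1, the synthase that makes HMG-CoA (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, 12.1% exon overlap), went from 1080 ± 108 to 732 ± 109 CPM (-0.56, SE 0.12, adjusted p = 0.0226). Fdps, farnesyl diphosphate synthase (26.7% exon overlap), fell by 0.97 on the log2 scale (SE 0.19) and lay between 29.4 and 33.7 CPM in 5 D316A-Tg libraries against 63.7 CPM in library 12. Hmgcs1 was still called with a term for lymphocyte-rich libraries. Fdps was then at -0.74 and not called (adjusted p = 0.0624).

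Macrophage genes had a median of -1.17 with 6 of 23 members lower, 12 adjusted over the list alone, such as the mannose receptor Mrc1 (-1.32, SE 0.33) and Cd14 (-1.14, SE 0.26). Collagen and matrix genes had a median of -0.86 with 3 of 30 lower, 14 adjusted over the list alone, such as the metalloprotease Mmp14 (-1.26, SE 0.29). Endothelial genes had a median of -0.63 with 5 of 13 lower, all 13 adjusted over the list alone, such as endomucin, Emcn (-0.81, SE 0.13). Camera adjusted p-values were 5.15e-08, 7.32e-09 and 2.25e-07, and the adjusted p was 0.511 for each with an estimated correlation. The lower macrophage and collagen scores were those of the lymphocyte-rich D316A-Tg libraries (3.391 to 4.245 and 5.96 to 6.678). D316A-Tg 10 and 12 scored 5.277 and 5.53 for macrophages, within the WT-Tg range of 4.853 to 6.54. For collagen and matrix they scored 7.656 and 7.863, within 7.402 to 8.359. Endothelial scores were 5.743 and 5.94, against 5.835 to 6.254 in WT-Tg. Inflammatory cytokines (-0.86, 2 of 20 lower, with the chemokine Cxcl1 falling 3.18-fold), smooth muscle and pericytes (-0.42, 3 of 12 lower, with the proteoglycan Cspg4 at -0.84), progenitors and fibroblasts (-0.45, 3 of 15 lower, with lumican, Lum, at -1.88), blood cells (-0.69, 1 of 6 lower) and cell division (-0.31, 0 of 15 called by edgeR) followed. Their camera adjusted p-values were 0.000642, 0.000758, 0.0131, 0.0147 and 0.0197, and with an estimated correlation the adjusted p was 0.511, 0.511, 0.586, 0.511 and 0.848. Mrc1, Cd14 and Mmp14 were at -0.83, -0.82 and -0.85 with a term for lymphocyte-rich libraries and not called (adjusted p = 0.143, 0.149 and 0.127). The smooth muscle median was then -0.19, and the calls of progenitors and fibroblasts (-0.22, 0.0601) and blood cells (-0.48, 0.0696) ended. Mature adipocyte genes were then called (0.14, adjusted p = 0.0349, and 0.694 with an estimated correlation as well). Leaving out single libraries ended the calls of Mrc1, Cd14, Mmp14 and Lum (highest adjusted p = 0.0789, 0.0524, 0.0638 and 0.0541).

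Lymphocyte lists had higher medians on HFD, of 1.91 for T and 1.89 for B lymphocytes, although edgeR called 0 of their 17 and 13 members (camera adjusted p = 2.59e-05 and 0.000582, and adjusted p = 0.586 for both with an estimated correlation). Lymphocyte-rich libraries were 1 of 6 in WT-Tg and 4 of 6 in D316A-Tg, and with a term for them, which the B lymphocyte score itself sets, the medians were 0.52 and 0.75. With that term edgeR called 0 of the 29 contractile genes, whose median was 5.10. The macrophage, collagen and endothelial medians with that term were -0.72, -0.50 and -0.41. The circadian clock list had a median of 0.36 with 4 of 15 higher, 8 adjusted over the list alone (0.0147, and adjusted p = 0.511 with an estimated correlation). D316A-Tg 12 scored 4.714 for the clock list, within the WT-Tg range of 4.496 to 4.78. The other D316A-Tg libraries scored 5.116 to 5.385.

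Among the largest decreases on HFD were Ncan, a chondroitin sulfate proteoglycan (ENSMUSG00000002341, chromosome 8, 70093085 to 70120873) (-2.74, SE 0.40, adjusted p = 0.00943), the guidance factor Slit2 (-2.85, SE 0.57), the receptor chain Il20rb (-2.33, SE 0.32), lipocalin 2, Lcn2 (-2.16, SE 0.51), and the scavenger receptor Olr1 (-3.05, SE 0.87). The calls of Lcn2 and Olr1 ended with a term for lymphocyte-rich libraries (-1.40 and -2.14, adjusted p = 0.239 and 0.103) and without single libraries (highest adjusted p = 0.0641 and 0.0992). Of the other lists, AMPK subunits (0.28), myogenic lineage (0.37), lipolysis (0.04), glucose uptake and glycolysis (0.16), mature adipocyte (0.11), mammary and luminal epithelium (-0.33), skin (-0.40), Schwann and neuronal (-0.24), immediate early response (-0.03) and sex-linked genes (-0.03) had camera adjusted p-values from 0.129 to 0.922. Means of the last 2 had the opposite sign to their medians.

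The number of HFD calls was 458, 607, 337, 384 and 326 without WT-Tg 1, 2, 4, 5 and 6, 639, 496, 393 and 535 without D316A-Tg 7, 8, 9 and 11, and 3919 without D316A-Tg 12. With a term for lymphocyte-rich libraries edgeR called 79 genes, 27 higher and 52 lower (34.2% higher against 53.3%), among them Ncan, Slit2, Il20rb, Hmgcs1, Emcn, Cxcl1, Lum and Cspg4 and no other gene named above for HFD. In the 7 libraries that were not lymphocyte-rich, 5 of WT-Tg and 2 of D316A-Tg, it called 0, with 1840 at an unadjusted p under 0.05. One of the 7, D316A-Tg 12, scored 2.32 for B and 1.49 for T lymphocytes, against at most 1.40 and 0.76 in the others. It may thus not be free of lymphocytes. Of the 1241 calls, 77 were also called with the term, and all 1241 kept their direction. In the 7 libraries 1238 of the 1238 that could be tested kept it. These genes were picked in the fit that holds the same libraries, so their kept directions are no separate evidence.

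**Figure D3:**
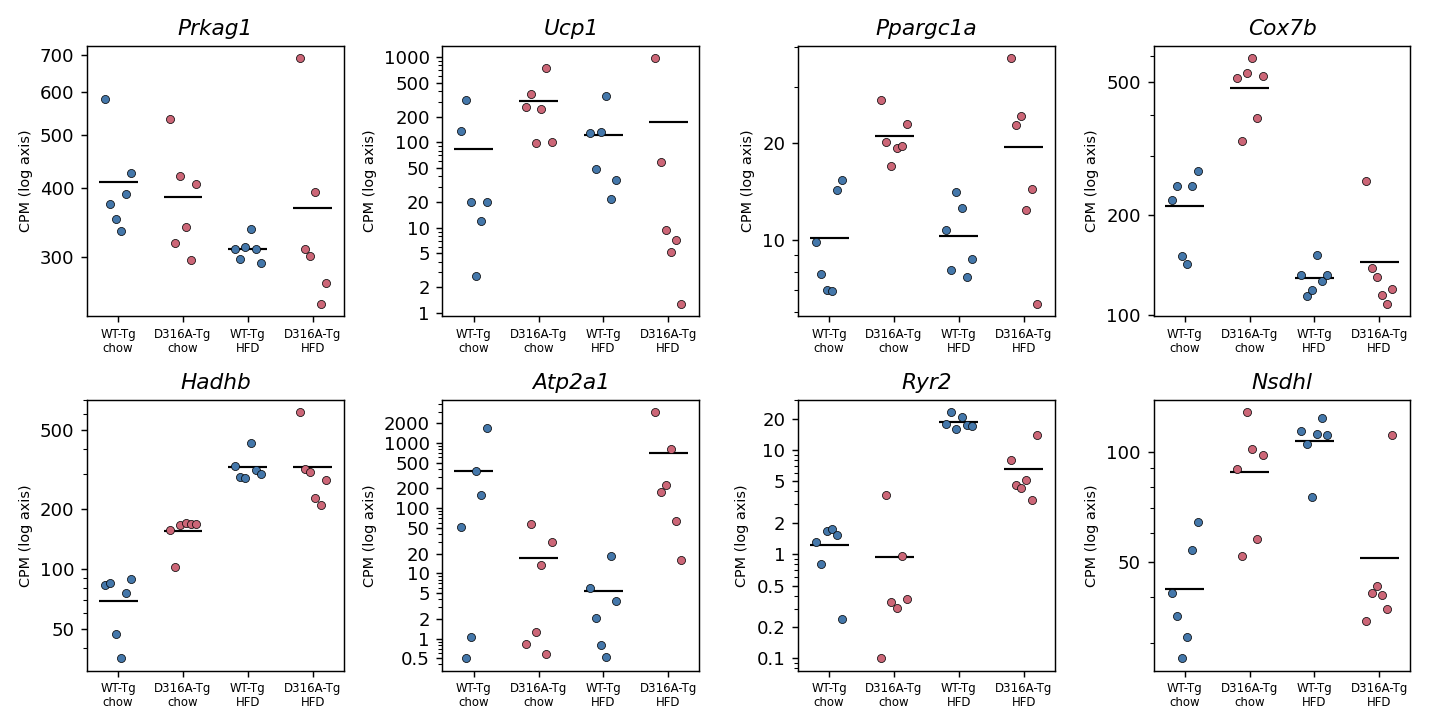
CPM of 8 genes in each library on log axes, by group (blue WT-Tg, red D316A-Tg); points are libraries, values under 0.1 CPM are drawn at 0.1, and horizontal lines are group means. Cox7b rose from a mean of 212 to 481 CPM on chow while Nsdhl was at 107 and 51.1 CPM on HFD, and Atp2a1 was at 703 CPM in HFD D316A-Tg.

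Whether the D316A effect differed between the 2 cohorts was tested with the difference of both log2 fold changes. Its median was negative for lists of cholesterol synthesis, oxidative phosphorylation and lipid metabolism, and positive for muscle and lymphocyte lists. Camera called 14 of 32 lists, and 0 with an estimated correlation (lowest adjusted p = 0.468). Nsdhl, a sterol dehydrogenase (ENSMUSG00000031349, chromosome X, 72918557 to 72958514), was at 42.1 ± 14.2 CPM in WT-Tg and 87.8 ± 28.7 CPM in D316A-Tg on chow, and at 107 ± 16.7 and 51.1 ± 29.4 CPM on HFD, a difference of -2.11 (SE 0.39, adjusted p = 0.00337). In all, 2080 of 16,072 genes differed, 977 with a more positive and 1103 with a more negative effect on HFD. The more positive ones were the larger number with voom (5586 and 4733), the replicate block (1433 and 1231) and terms for lymphocyte-rich libraries (1023 and 856). Age and batch differ along with the diet, so the difference is between cohorts.

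Cholesterol synthesis had a median difference of -1.07 with 13 of 22 members lower and 1 higher, 18 and 1 adjusted over the list alone, including Idi1 (-1.45, SE 0.25). Oxidative phosphorylation had a median of -0.73 with 26 of 75 lower, 62 adjusted over the list alone, including Ndufs5 (-1.81, SE 0.39), and fatty acid oxidation one of -0.88 with 7 of 25 lower, 17 adjusted over the list alone, including the reductase Decr1 (-1.24, SE 0.29). The TCA cycle median was -0.75 with 6 of 17 lower, that of de novo lipogenesis -0.86 with 9 of 20 lower, and that of triglyceride synthesis -0.88 with 3 of 11 lower. Camera adjusted p-values of these 6 lists were 3.46e-10, 2.54e-19, 3.85e-08, 9.33e-07, 0.000107 and 0.00213, and the lowest adjusted p with an estimated correlation was 0.468, for cholesterol synthesis. Contractile genes had a median of 8.04 with 26 of 32 higher, 29 adjusted over the list alone, and calcium cycling genes one of 5.15 with 11 of 19 higher and 1 lower (1.33e-12 and 8.2e-05, and adjusted p = 0.624 for both with an estimated correlation). Cacna1s, a calcium channel of muscle, had a difference of 9.16 (SE 1.58, 20% exon overlap).

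Differences were also called for brown and beige adipocyte genes (-0.31, 2 of 22 lower), mitochondrial genome transcripts (-0.61), collagen and matrix (-0.77), T and B lymphocytes (3.14 and 3.65) and sex-linked genes (-0.47, 2 of 4 lower). Their camera adjusted p-values were 0.0122, 0.00867, 0.00104, 0.000147, 0.00025 and 0.0122, and the lowest adjusted p of them with an estimated correlation was 0.624. With terms for lymphocyte-rich libraries the medians were -0.92 for brown and beige adipocyte, 0.64 for T and 1.46 for B lymphocytes and -0.49 for triglyceride synthesis. The collagen call ended (-0.01, adjusted p = 0.821), and 5 lists were called in addition, 18 in all. These were endothelial (0.48), smooth muscle and pericyte (0.80), creatine cycling (0.74), myogenic lineage (1.08) and mammary and luminal epithelium (-2.22), with adjusted p-values of 0.00201, 0.0113, 0.0248, 0.0385 and 0.0468. With an estimated correlation as well these were 0.453, 0.405, 0.405, 0.405 and 0.603. Median, mean and direction of the test did not all share a sign for glucose uptake and glycolysis (-0.46 and 0.35), inflammatory cytokines and endothelial genes, none of them called. The largest single differences were those of the seminal vesicle gene Svs5 (16.86, SE 4.29), which rested on 1200 CPM in chow WT-Tg 6 and lay at 0 in all WT-Tg HFD libraries, Trim54 (12.20, SE 2.18, 26.6% exon overlap) and Myh4 (11.93, SE 2.81), and in the other direction Lcn2 (-4.07, SE 1.04), Gipc2 (-3.93, SE 0.76, 20.9% exon overlap), Ncan (-3.47, SE 0.63) and the copper oxidase Hephl1 (-3.36, SE 0.81). With terms for lymphocyte-rich libraries the calls of Svs5 and Lcn2 ended (adjusted p = 0.0862 and 0.0619). Ucp1 (-1.30, SE 1.75, adjusted p = 0.623) and Prkag1 (0.35, SE 0.29, adjusted p = 0.405) did not pass. The count was 3329, 3142 and 4304 without chow WT-Tg 5, WT-Tg 6 and D316A-Tg 8, 1383 without chow WT-Tg 3 and 1368 without HFD D316A-Tg 11.

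Calls of both diets were compared over the 14,098 genes tested in both, 1265 of them called on chow and 1198 on HFD. Genes named here that were lower in D316A-Tg on both diets were Vwf, Notch3, Eng (-0.83 on chow and -0.60 on HFD), Egfl7 (-0.94 and -0.87, 11.2% exon overlap) and Pdgfrb (-0.74 and -1.08). Those higher on both were Thrsp (2.59-fold and 3.19-fold) and Acacb (2.30-fold and 2.52-fold). No list was tested for the shared genes. There were 38 genes higher and 46 lower in both, against 35.2 and 19.4 for independent lists, and 40 called in opposite directions against 53. The log2 fold changes correlated with a Pearson r of -0.26 and a Spearman rho of -0.05 across genes, which are not independent replicates. Both comparisons share no libraries. The number shared was 360 with DESeq2 and 27 with terms for lymphocyte-rich libraries. Of the 84, 9 were called on both diets with those terms, 4 higher and 5 lower. Pdgfrb was among them. Vwf, Notch3, Eng, Egfl7, Thrsp and Acacb were then at -0.61, -0.69, -0.41, -0.67, 0.99 and 0.79 on HFD and not called there (adjusted p = 0.0765, 0.0704, 0.0705, 0.0738, 0.181 and 0.355).

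The last comparison set HFD WT-Tg against chow WT-Tg, which differ in diet, in age, in base-calling software and in the count table that holds them. It therefore describes a difference between cohorts. Lists of matrix, cholesterol synthesis, mitochondrially encoded and macrophage genes had higher medians in the HFD cohort, and camera called 0 lists with an estimated correlation (adjusted p = 0.98 for each of the 4). Col12a1, a fibril-associated collagen (ENSMUSG00000032332, chromosome 9, 79598991 to 79718831), was at 5.09 ± 1.6 CPM in the chow and 44.2 ± 19.7 CPM in the HFD cohort (log2 fold change 3.24, SE 0.30, adjusted p = 2.29e-06), and Mmp12, a macrophage elastase, at 7.8 ± 7.36 and 87.7 ± 36.7 CPM (3.63, SE 0.64). In all, 9304 of 15,018 genes were called, 4306 higher and 4998 lower.

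Collagen and matrix genes had a median of 1.16 with 19 of 30 higher, cholesterol synthesis one of 0.73 with 15 of 22 higher and 1 lower, mitochondrial genome transcripts one of 1.10 with 8 of 13 higher, and macrophage genes one of 0.92 with 10 of 23 higher and 1 lower. The same counts adjusted over the list alone were 19, 15 and 1, 8, and 9 and 1. Camera adjusted p-values were 0.000235, 0.0023, 0.000674 and 0.0412, and the adjusted p was 0.98 for each with an estimated correlation. Genes of the mitochondrial genome together held 3.77% to 7.37% of counts in chow and 5.05% to 6.96% in HFD WT-Tg libraries. Their total was thus not higher in the HFD cohort, although the list median was. The list mean was 2.26, so some of its genes differed far more than others. Whether read counting sets this was not tested. That median was 0.76 with a mean count of at least 50. The macrophage call was lost without any of 5 libraries (highest adjusted p = 0.0907) and with a mean count of at least 50 (0.85, adjusted p = 0.0565). Hmgcs1 rose 5.67-fold. The lipase Lipf (161-fold) was among the largest increases, and the fructose transporter Slc2a5 (98.4-fold lower), Apol7c (135-fold lower, adjusted p = 0.103 with terms for lymphocyte-rich libraries), Atp2a1 (66.5-fold lower) and Ckm (56.8-fold lower) were among the largest decreases. Contractile genes had a median of -4.17 with 22 of 28 lower (camera adjusted p = 0.0839), and T and B lymphocyte genes -3.37 and -3.33 (0.0839 and 0.263). With terms for lymphocyte-rich libraries camera called the contractile list (-4.96, adjusted p = 0.00512) and cell division (1.31, adjusted p = 0.0114), with an adjusted p of 0.992 for both with an estimated correlation as well. Median, mean and direction of the test did not all share a sign for AMPK subunits, creatine cycling, sarcoplasmic calcium cycling, oxidative phosphorylation, smooth muscle and pericyte, skin and immediate early genes, none of them called. The glycolytic enzyme Gapdh, present at high levels in most tissues, was at 4.31 to 9.38 CPM in the chow table and at 398 to 1390 CPM in the HFD table. Processed pseudogenes held 1.67% to 3.13% of counts in chow and 0.161% to 0.303% in HFD libraries. Ucp1 (0.67, SE 1.01, adjusted p = 0.582) and Prkag1 (-0.28, SE 0.14, adjusted p = 0.09) did not differ past the threshold. Prkag1 passed it with upper-quartile scaling (-0.36, adjusted p = 0.0364) and with a mean count of at least 50 (-0.35, adjusted p = 0.033).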

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

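Of the tests weighed here, those of the genotype as the whole cause of lymphocyte content, of calcium genes without contractile genes, of the genotype on both diets or on HFD alone, of diet, age or batch, and of the parent genes of pseudogenes were chosen after results had been seen. A library was listed when its gap to the nearest other library of its group was above Dixon's 95% bound for 6 values. This held for 15 of 218 tests, and chance lists about 1 in 20.

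On chow the smooth muscle and pericyte score was 5.56 in WT-Tg 5 (others 4.3 to 4.73), and log2 CPM of Hadhb was 6.67 in D316A-Tg 8 (others 7.29 to 7.4). On HFD, WT-Tg 4 lay above its group in oxidative phosphorylation (7.25), mitochondrial genome transcripts (8.2), TCA cycle (8.37) and fatty acid oxidation (8). D316A-Tg 7 lay above its group in oxidative phosphorylation (7.65) and mitochondrial genome transcripts (8.75), and D316A-Tg 10 below it in de novo lipogenesis (7.16). WT-Tg 3 stood out by its T lymphocyte (4.8) and B lymphocyte (5.83) scores and WT-Tg 5 by its circadian clock score (4.5). D316A-Tg 12 had log2 CPM of 6 for Fdps, 10.3 for Cfd and 1.68 for Olr1, apart from the other 5 libraries.

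The D316A effect differed between cohorts for 2080 genes by the test of the difference. Differences of log2 fold changes were 16.9 for Svs5, 12.2 for Trim54, 11.9 for Myh4, 9.16 for Cacna1s, -3.47 for Ncan, -3.93 for Gipc2, -4.07 for Lcn2, -3.36 for Hephl1, -1.45 for Idi1, -2.11 for Nsdhl, -1.81 for Ndufs5 and -1.24 for Decr1. Median differences of lists were -0.309 for brown and beige adipocyte, 5.15 for sarcoplasmic calcium cycling, 8.04 for skeletal muscle contractile, -0.727 for oxidative phosphorylation, -0.608 for mitochondrial genome transcripts, -0.747 for TCA cycle, -0.879 for fatty acid oxidation, -0.86 for de novo lipogenesis, -0.884 for triglyceride synthesis, -1.07 for cholesterol synthesis, -0.772 for collagen and matrix, 3.14 for T lymphocyte, 3.65 for B lymphocyte and -0.465 for sex-linked genes.

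Relabelled splits of the libraries show how often a random grouping gives as many calls. Of 100 splits, the real one included, 2 called as many genes on chow (highest other 6327), 3 on HFD (2816), 2 for the difference between diets (2199) and 1 between cohorts (3931), and 2 splits shared as many calls between diets (218). The other splits that reached the counts on chow (6327) and HFD (2816 and 1529) held 5 lymphocyte-rich libraries in 1 arm, against 4 in the real splits, which points to a structure of the libraries, although 3 more chow splits of that kind called 0 genes. For the number of lists called, 5, 18, 54 and 99 of 100 splits reached the real count, so a random grouping is not excluded for these 4 counts.

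Lymphocyte genes were high in some libraries of every group, and lymph node tissue in the sample, blood and the genotype were weighed. By lymph node stroma markers, 11 of 11 lymphocyte-rich libraries lay above every other library of their diet, as lymph node tissue predicts. The number was also 11 by the 5 markers that are in none of the lists. Glycam1, made by lymph node vessels, was at 37.5 to 67 CPM in the lymphocyte-rich libraries on chow and at most 0.0817 CPM in the others. Chst4 (3.39 to 5.13 against at most 0.118 CPM) and Cxcl13 (54.6 to 152 against at most 6.69 CPM) were higher in them too. Ccl19 and Ccl21a were at most 0.059 CPM in all 12 chow libraries, and Madcam1 overlapped (1.12 to 4.79 against up to 1.38 CPM). By blood cell genes 0 of 11 lay above the others, which argues against blood. That 4 of 4 groups held libraries of both kinds is the pattern that prompted the question, and it argues against the genotype as the whole cause. Lymph node tissue stays open, as the protocol says that the node was removed; Ccl19 and Ccl21a decide nothing on chow, since on HFD they were higher in lymphocyte-rich libraries (0.957 to 7.63 and 34 to 146 CPM) than in the others (at most 0.355 and 2.59) and the chow table also holds few counts of Gapdh.

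Skeletal muscle genes were higher in HFD D316A-Tg, and muscle tissue in the sample was weighed against an effect of the genotype. A second muscle list had a median of 4.52, with 19 of 23 genes higher and 0 lower. This is within 2 of the contractile median of 5.50, as muscle tissue predicts. Its mean CPM in chow WT-Tg and HFD D316A-Tg correlated with a Spearman rho of 0.561. That is below the 0.7 set in advance for muscle tissue and above 0.5, which cannot tell. The 2 groups lie in 2 tables, and a difference in counting could lower rho even where both hold muscle. The contractile median was 2.28 above the calcium cycling median, so calcium genes did not rise without the contractile ones, as the contractile calls had already shown. Between diets 26 contractile genes differed, so their change was not the same on both. On chow 0 of 29 were called and WT-Tg muscle scores ran from 0.31 to 6.93. If muscle tissue sets those scores, the chow comparison cannot exclude a genotype effect on both diets. With the muscle score as covariate 0 genes were called on HFD, which cannot tell because score and genotype correlated at 0.829. Muscle tissue in the sample and a genotype effect, on HFD or on both diets, are thus left open.

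Counts of some genes differed between the tables in a way that a counting difference predicts. Of 4 genes at 0 in all chow libraries and at least 5 CPM in HFD, 1 had an exon overlap value, so this test, of overlapping genes and of diet or age, is void. Processed pseudogenes held more of the chow counts, and 250 genes with such a pseudogene had a median HFD over chow log2 fold change of 0.718, which is 0.712 above that of other genes and outside the 0.0468 to 0.276 that held 95% of the medians of 10,000 matched random lists. This is consistent with reads of parent genes being counted on pseudogenes in the chow table, a test added after the first proved void and after the pseudogene share and Gapdh had been seen. Each table holds 1 diet, so diet, age or batch cannot be told from counting. Of the 250 genes 161 were called higher in the HFD cohort and 27 lower. Counting can set such calls, so they are not read as effects of diet or age.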

How the results depend on the processing

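Terms for lymphocyte-rich libraries, alone, with the muscle covariate or with an estimated correlation, fits without those libraries, and the cohort fit without genes at 0 in one table (9297 calls) were chosen after the data were seen; the other settings were fixed before. Counts with RLE, upper-quartile scaling, a mean count of at least 50 and no robust step stayed within 1.5 times in every comparison, and no setting moved the cohort count of genes by more (8613 to 10263 without single libraries). For most values below the cause was not tested.

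On chow (1303) DESeq2 called 2931 genes, voom 10826, no filter 524, the fit of all 24 libraries 3615, the muscle covariate 67, the B lymphocyte covariate 3729, lymphocyte terms 4412, and libraries below the bound 2305; leave-one-out gave 140 to 3360. On HFD (1241) these were 2937, 4312 and 795, then 0 with the muscle covariate, 24 with the B lymphocyte covariate, 79 with lymphocyte terms, 0 below the bound and 0 with lymphocyte terms plus the muscle covariate; leave-one-out gave 326 to 3919. The difference between diets (2080) was 10319 with voom and 1368 to 4304 in leave-one-out. The overlap (84) was 360 with DESeq2, 27 with lymphocyte terms and 14 to 203 in leave-one-out.

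Lists called (22, 16, 14 and 4) were 0 in each comparison with an estimated correlation, also with lymphocyte terms, and 12, 10, 9 and 7 with fry; leave-one-out gave 18 to 23, 14 to 17, 14 to 16 and 3 to 5. Reversed values were -0.2546 for brown and beige adipocyte genes on HFD and -3.705 for Ucp1 on HFD with lymphocyte terms, with the same median under an estimated correlation, and in leave-one-out -0.004165 for oxidative phosphorylation and -0.02588 for Prkag1 on HFD and -0.01128 for Ucp1 between cohorts. Of the genes named, 29 were weaker in leave-one-out, 24 with lymphocyte terms and 10 with no filter.

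Replicate numbers do not pair libraries: 4 of 12 numbers correlated best with their own, and the replicate block gave 2664 and 8380 calls for the difference between diets and between cohorts. On chow 29 of 100 simulated 2-fold changes were recovered.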

Other observations

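The following were picked after results had been seen, and no test was added for them. Prkaa1, the catalytic α1 subunit of AMPK, rose on HFD from 59.3 to 72 CPM (log2 fold change 0.28, adjusted p = 0.0389), the 1 member of 7 AMPK subunit genes called there, and 0 of 7 were called on chow. This call ended without any of 10 libraries (highest adjusted p = 0.0884), with terms for lymphocyte-rich libraries (0.24, adjusted p = 0.168) and with no filter (adjusted p = 0.072). Collagen and matrix genes on chow had a median of -0.20 (adjusted p = 0.242), and with a term for lymphocyte-rich libraries a median of -0.53 with 17 of 30 lower (camera adjusted p = 2.49e-06, and adjusted p = 0.291 with an estimated correlation). Of the lists that camera called, some had medians that 10 or more of 100 splits reached. On chow these were calcium cycling (14), contractile (17), T lymphocyte (18), lipolysis (26) and cell division (31), and on HFD T lymphocyte (11), smooth muscle and pericyte (12), B lymphocyte (14), cell division (32) and oxidative phosphorylation (51). For the difference between diets they were mitochondrial genome transcripts (17), collagen and matrix (17) and brown and beige adipocyte (79), and 0 lists between cohorts.

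The Y-linked genes Ddx3y and Uty, higher in D316A-Tg on chow, were at similar levels on HFD, 180 ± 9.44 and 174 ± 16.8 CPM for Ddx3y and 40.3 ± 2.51 and 39.7 ± 3.94 CPM for Uty (SD, n = 6). Whether the chow groups differ in strain or Y chromosome was not tested. Such a difference would go along with the genotype in every chow comparison and in the difference between diets. The seminal vesicle gene Svs5 was at 1200 CPM in chow WT-Tg 6 and between 0.132 and 1.03 CPM in the other 5 libraries of that group.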
